A study of Mus musculus with 6 samples.

How the data were processed

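RNA of uterine epithelium, separated with pancreatin and dispase, was extracted with Trizol, amplified from 100 ng, labelled with biotin and hybridised to 1-colour Affymetrix 3′ expression arrays, 1 per sample, per the labels' protocols. Samples were grouped by genotype and day from their titles: WT on day 1 (302 and 303), WT on day 4 (277 and 284) and Sox17 heterozygous on day 4 (253 and 281). No labels pair samples across groups or name a batch, and no 2 arrays were identical.

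The deposited values are probe set signals, an intensity on a linear scale, made by the authors with software that the submitters' processing notes name as RMA, Affymetrix Expression Console and Transcriptome Analysis Console, without versions or roles. The values do not have the form of RMA output, which is on a log2 scale and has equal quantiles: the mean of each array after trimming 2% at each end was 500 and the quantiles differed. Which summary the authors used is not given in the sources used here. No detection calls were used, so whether a dim signal lies above background is unknown, and a signal under 50 is best read as low.

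The 45101 probe sets were named with the platform's gene annotation. Of these, 34945 had 1 gene symbol, 932 had several, 9160 had none listed and 64 were controls; only the first were used. Gene IDs of 34741 were found in a RefSeq gene table (assembly GRCm38.p6, used for names only), which changed 0 symbols. Each of the 18193 genes was represented by its probe set with the highest mean log2 value over the 6 arrays, and 9010 genes had more than 1. Values were taken as log2(signal + 1), with no further normalization and no filter, and fold changes are on that scale, which understates changes of dim genes.

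All 6 arrays were fitted in limma 3.58.1 (R 4.3.3) with a coefficient per group, so that the 3 groups shared an estimate of the spread with 3 residual degrees of freedom. The contrasts were WT day 4 minus WT day 1 and Sox17 heterozygous minus WT day 4, tested with eBayes at its default settings and Benjamini-Hochberg adjustment over all genes, at an adjusted p under 0.05. Counts of genes with an at least 2-fold change at an unadjusted p under 0.05 describe the data and are not called significant. With 2 arrays against 2 an exact permutation test cannot go below p = 0.333, so none was run. Errors after ± are limma's standard errors of the log2 change from eBayes at its default settings, also where a trend p-value stands beside them.

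Before the data were examined, 29 gene lists (pathways, hormone responses, epithelial classes, markers of other cell types and chromosome 1 neighbours of Sox17) were fixed and later tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison; a list needed 5 measured genes. Camera sets a list against all other genes, while fry, tried as an alternative, asks whether its genes move one way on balance. The rule for named genes was fixed at the same time: Sox17 first, the 10 largest increases and decreases past the threshold without overlap between arrays (filled up with genes at an unadjusted p under 0.05 where too few passed, predicted names left out), at most 4 genes of smallest p per list, and Ltf, Muc1, Lif, Ihh, Areg, Pgr, Esr1, Foxa2, Msx1, Wnt7a and Mki67 where measured. Areg had no probe set with a single symbol.

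The relation between the comparisons was described by correlation, covariance and overlap of calls, beside 100 simulations of unchanged groups drawn with each gene's fitted spread, equal in all groups. The fits were tested on simulated data before use, with 200 changed genes in each of 20 data sets for the heterozygous comparison. Each gene's spread was taken from the fit with an intensity trend, equal in all groups and independent between genes, which favours that fit. The default fit found 6.55% of log2 changes of 3 and 0% of log2 changes of 1 in the brighter part of the genes, and the fit with an intensity trend 96.4% and 48.5%. In the dimmer part the trend fit found 18.1% and 0.198%. Of all calls, 4.35% and 6.54% were false. Camera passed at an unadjusted p under 0.05 in 3.25% of 400 unchanged lists and in 20 of 20 raised ones. Because the simulated genes were independent, this could not show false list calls that arise from genes that move together.

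Alternatives fixed beforehand were quantile normalization, centring on the median, leaving out the dimmest genes, an intensity trend or robust prior in eBayes, fits on 4 arrays, array weights, the mean of a gene's probe sets, every probe set on its own, leaving out each array, an adjusted p of 0.10 or a 2-fold minimum, camera with an estimated correlation, fry, and splits of the WT day 4 arrays. Pseudocounts of 32 and 100, a minimum mean signal of 200 and further variants of the trend fit were chosen after seeing the data.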

Results

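Uterine epithelium from pregnant mice was profiled on 6 Affymetrix expression arrays, 2 in each of 3 groups. The groups were wild-type (WT) mice on day 1 of pregnancy, the day the vaginal plug was found, WT mice on day 4, and mice on day 4 that carried a GFP allele of Sox17 beside a normal one (Sox17 heterozygous). SOX17 is a transcription factor of the uterine epithelium. On day 1 the mouse uterus is under estrogen and the epithelium divides, while by day 4 progesterone prevails and the uterus becomes ready for the embryo. The samples carry different numbers, which look like those of separate animals, but nothing states so, and p-values therefore measure only the spread between these samples. The 2 arrays per group limit the precision of every value.

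Each array had the same trimmed mean signal of 500, but 1 array differed from the rest in its dim range. WT day 4 array 277 had a median signal of 138, against 66.2 to 78.0 on the other 5 arrays, and 27.0% of its probe sets had signals below 50, against 41.6% to 44.6%. The WT day 4 pair accordingly differed most, with a median absolute log2 difference of 0.59 per gene, against 0.32 in the day 1 pair and 0.28 in the heterozygous pair. The 3′ minus 5′ log2 difference of the Gapdh control probe sets lay between -0.75 and -0.52 on all 6 arrays, and that of the Actb control between 0.25 and 0.50. The spiked-in hybridisation and poly-A controls each read highest on array 277, such as CreX at 33878 against 24458 to 27547. Both heterozygous arrays read lowest for BioB (422 and 383 against 451 to 611), BioC, BioDn, lys and dap, but not for CreX, phe and thr. Whether this technical difference between groups moved other signals was not tested.

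**Figure D1:**
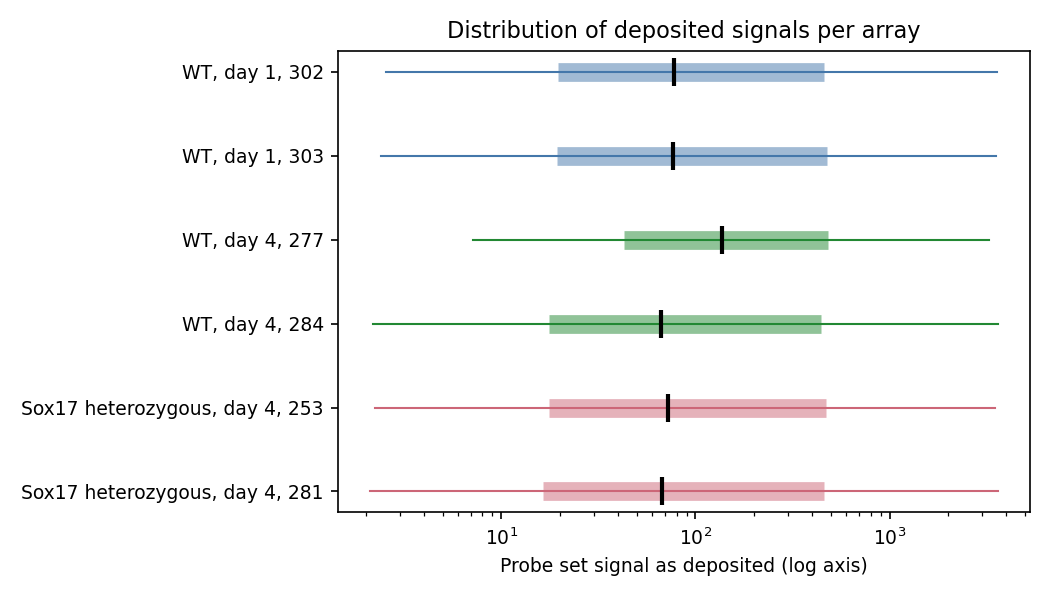
Deposited probe set signal on each array (log axis): thin lines run from the 5th to the 95th percentile, thick bars from the 25th to the 75th, and the black mark is the median. The median of WT day 4 array 277 is 138, and those of the other 5 arrays lie between 66.2 and 78.0.

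The first comparison set WT epithelium on day 4 against day 1. Sox17 rose, from signals of 7738 and 8671 on the day 1 arrays to 34794 and 35060 on day 4 (log2 change 2.09 ± 0.19, SE, n = 2 arrays per group, adjusted p = 0.00964). Its other probe set rose from 2394 and 2478 to 22781 and 18473 (3.07 ± 0.23 in the fit over every probe set). Progesterone-induced genes rose as a list (median log2 change 2.30, camera adjusted p = 0.000204), among them Ihh (5.09 ± 0.27), a signal from epithelium to stroma, while estrogen-induced epithelial genes fell (median -4.35, camera adjusted p = 6.72e-10), among them the mucin Muc1 (-4.10 ± 0.27). Lists of the interferon response, cholesterol synthesis and endoplasmic reticulum folding also fell (medians -1.82, -1.22 and -0.93). With an estimated correlation no list passed, the smallest adjusted p being 0.330. That setting leaves camera 3 residual degrees of freedom, so it cannot tell an effect of correlation from that of few arrays. The progesterone list had an estimated correlation of -0.046, under the preset 0.01, and still did not pass.

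Of 18193 genes, 1379 rose and 1042 fell at an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment, and 2342 and 1657 changed at least 2-fold at an unadjusted p under 0.05. Among the 10 largest increases were Npl, an enzyme that splits sialic acid (12.20 ± 0.51), the glucose transporter Slc2a3 (10.45 ± 0.72), the endocytic receptor Lrp2 (9.41 ± 0.27) and the peptidase Mme (8.96 ± 0.27). Fam107a, the transporters Slc16a12 and Slc5a11, Rims3, Gldc of glycine breakdown and Acod1, which makes itaconate, rose by 8.22 to 9.06. Lrg1 (fell by 10.88 ± 0.75), the arginase Arg1 (fell by 9.86 ± 1.35) and Olfm1 (fell by 9.15 ± 0.86) had the largest decreases. They were followed by Pglyrp1, Hsd17b2, which inactivates estradiol, the cytokine Il1a, Pla2g2e, Clca3a2, Golm1 and Apobec2, with changes between -8.50 and -7.75. Npl had signals of 4 and 12 on day 1 and 37448 and 35335 on day 4, and folds against signals this dim depend on the pseudocount of 1.

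Of 14 measured estrogen-induced epithelial genes, 10 fell and 4 did not pass (12 fell adjusted over the list alone), with a median log2 change of -4.35 (camera adjusted p = 6.72e-10, and adjusted p = 0.383 with an estimated correlation). Muc4 (-6.63 ± 0.39), the arginine deiminase Padi1 (-6.98 ± 0.58) and the cornified envelope gene Sprr2f (-3.85 ± 0.33) fell. Lactoferrin (Ltf) had signals of 35131 and 37791 on day 1 and of 8351 and 1406 on day 4 and did not pass (-3.41 ± 0.97, adjusted p = 0.0992). Of 13 progesterone-induced genes, 7 rose and 6 did not pass (8 rose and 1 fell adjusted over the list alone), with a median of 2.30 (camera adjusted p = 0.000204, and adjusted p = 0.330 with an estimated correlation), which was 3.55 without the dimmest genes. Besides Lrp2, Ihh and Sox17, these included the histidine decarboxylase Hdc (3.88 ± 0.33).

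Among 14 steroid receptors and cofactors, 4 rose and 10 did not pass (5 rose adjusted over the list alone; camera adjusted p = 0.504). The progesterone receptor Pgr rose by 2.72 ± 0.51, Gata2 by 1.86 ± 0.20, and the receptor chaperones Fkbp5 and Fkbp4 by 3.21 ± 0.36 and 1.37 ± 0.27, while the estrogen receptor Esr1 was at 0.39 ± 0.29 (adjusted p = 0.441). Of 27 implantation and receptivity genes, 4 rose and 7 fell (5 and 8 adjusted over the list alone; median -0.23, camera adjusted p = 0.0926), and the list passed as lower without WT day 4 array 284 (median -0.29, 0.0401). The lysophosphatidic acid receptor Lpar3 rose by 3.83 ± 0.20, the homeobox gene Msx1 by 2.44 ± 0.20, and the growth factor Hbegf fell by 3.11 ± 0.22. The cytokine Lif, needed for implantation, fell by 5.83 ± 0.41. In the luminal epithelium list, 2 of 7 genes rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.667, and 0.0455 over every probe set), with the calcium-binding protein Calb1 up by 5.11 ± 0.23 and the receptor Met down (-3.54 ± 0.32). In the glandular epithelium list, 1 of 11 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.896), with Aldh1a1 at 1.89 ± 0.26 and Wnt7b at -2.83 ± 0.35. Foxa2, a gland transcription factor, was at -0.10 ± 1.02 and Wnt7a at 1.71 ± 0.36 (adjusted p = 0.964 and 0.0512).

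Interferon response genes fell in 8 of 23 cases and 15 did not pass (19 fell adjusted over the list alone), with a median of -1.82 (camera adjusted p = 1.72e-11, and adjusted p = 0.423 with an estimated correlation). Examples were the chemokine Cxcl10 (-5.63 ± 0.34), the viral RNA sensor Oas1a (-2.64 ± 0.22) and Gbp3 (-3.87 ± 0.60). In cholesterol synthesis, 7 of 20 genes fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -1.22 (camera adjusted p = 6.95e-07, and adjusted p = 0.522 with an estimated correlation). The sterol enzymes Msmo1, Cyp51 and Idi1 fell, with changes of -2.82 ± 0.28, -2.58 ± 0.26 and -2.57 ± 0.30. Of 20 endoplasmic reticulum chaperone and stress genes, 7 fell and 13 did not pass (14 fell and 1 rose adjusted over the list alone), with a median of -0.93 (camera adjusted p = 1.35e-07, and adjusted p = 0.330 with an estimated correlation). Xbp1, a transcription factor of secretory cells, fell by 2.16 ± 0.19, and Edem1 fell by 2.49 ± 0.18.

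Epithelial junction genes were called down as a list, with 3 rising and 6 falling among 31 (3 and 9 adjusted over the list alone) and a median of -0.38 (camera adjusted p = 0.00241). The gap junction genes Gja1 (-6.68 ± 0.23) and Gjb2 (-2.89 ± 0.19) fell. General epithelium genes, with 1 of 18 rising and 4 falling (1 and 6 adjusted over the list alone), had the same median and p, and the keratin Krt7 fell by 2.33 ± 0.20 while Cldn3 rose by 1.39 ± 0.21. Of 26 immediate early and dissociation response genes, 2 fell and 1 rose (2 and 1 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.00133). Ier3 fell by 2.27 ± 0.26, the heat shock gene Hspa1a fell by 2.11 ± 0.36, and Nr4a1 rose by 1.55 ± 0.19. For these 3 lists the estimated correlation gave an adjusted p = 0.383, and without WT day 4 array 277 the adjusted p-values were 0.0818 for junctions (median -0.27), 0.112 for general epithelium (-0.41) and 0.0702 for immediate early genes (-0.43). The junction call also ended above a mean signal of 200 (median -0.20, 0.0576) and the general epithelium call over every probe set (-0.18, 0.129). The junction median was -0.59 after centring on the median, -0.71 with the mean of a gene's probe sets, -0.67 over every probe set, and -0.22 both without the dimmest genes and with a pseudocount of 32; that of general epithelium was -0.59 after centring.

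Division genes did not pass as lists on day 4. Against the background given above, the arrays did not show more mitotic signal on day 1. The mitotic list had medians of 5.83 and 5.56 on day 1 and of 7.36 and 6.13 in WT on day 4 (log2). Of 27 mitotic genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 1.20, camera adjusted p = 0.0926), and of 27 DNA replication genes, 5 rose (11 rose and 2 fell adjusted over the list alone; median 0.77, adjusted p = 0.0780). Top2a rose by 2.45 ± 0.36 and Tyms by 3.63 ± 0.33, whereas Mki67 was at -0.18 ± 0.87. The mitotic list passed without WT day 4 array 284 (median 1.82, adjusted p = 0.000386), without day 1 array 302 (0.0405), after centring on the median (0.0133), with array weights (0.0453) and over every probe set (0.0197). Without array 277 its median was 0.38 (0.357). The DNA replication list passed over every probe set (0.0134). In the WNT list, 3 of 31 genes rose and 4 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.740). The receptor Fzd6 rose by 2.71 ± 0.20 and the ligands Wnt11 and Wnt5a by 4.69 ± 0.39 and 2.66 ± 0.25. In the Notch list, 1 of 20 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 1.00), with the target gene Hey2 at 5.28 ± 0.21 and Hey1 at -3.67 ± 0.18. Ihh was the only riser among 13 Hedgehog genes (1 adjusted over the list alone; camera adjusted p = 0.671). Among 12 SOX genes, 2 rose and 3 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.956), with Sox5 at 6.67 ± 0.26, Sox9 at -4.05 ± 0.42 and Sox4 at -2.12 ± 0.26.

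Of 22 ion and water transport genes, 3 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.330). The anion exchanger Slc26a4 fell by 6.69 ± 0.37 and the sodium channel subunit Scnn1a rose by 1.95 ± 0.23. Of 18 prostaglandin genes, 4 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.602), with the reductase Ptgr1 at 4.92 ± 0.28 and the receptor Ptger2 at 3.05 ± 0.29. Markers of stroma, smooth muscle, endothelium, macrophages, neutrophils, lymphocytes, erythrocytes and oviduct had camera adjusted p-values from 0.330 to 1.00. Over all genes tested, 0 or 1 stroma, smooth muscle, endothelium, neutrophil, lymphocyte or erythrocyte marker passed in either direction; 2 macrophage markers rose and 2 fell, and 2 oviduct markers rose. Adjusted over the list alone, 1 stroma marker fell, 1 smooth muscle marker rose and 2 fell, 1 endothelium marker rose and 1 fell, 3 macrophage markers rose and 2 fell, 1 neutrophil marker fell and 2 oviduct markers rose. Among these were the stromal gene Fbln1 (-4.33 ± 0.31), the macrophage genes Cd68 (-5.01 ± 0.39) and Lyz2 (2.42 ± 0.25), and the oviduct glycoprotein Ovgp1 (4.86 ± 0.47). Of 23 neighbours of Sox17 on chromosome 1, Arfgef1 fell (-1.35 ± 0.19; 1 gene adjusted over the list alone; camera adjusted p = 0.690).

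The median change of all genes with day was 0.30, and it was 0.15 after quantile normalization and 0.09 after centring each array on its median, which moved the share of increases among calls from 57.0% to 44.5%. Without day 1 array 302 or 303, limma called 0 genes, with 3740 and 3946 at an unadjusted p under 0.05 and 3177 and 3458 called with an intensity trend, and 616 passed without either heterozygous array. For 7 lists (glandular, WNT, Notch, SOX, endothelium, neutrophil and lymphocyte) and the chromosome 1 neighbours the median lay above 0 while the camera direction, which is against all other genes, was down, and the glandular mean was -0.08 and that of the neighbours -0.06. Either scaling turned the median below 0 for WNT, SOX, oviduct and chromosome 1 genes, and centring on the median that of steroid receptors. Another probe set had the opposite sign for Apobec2, Fkbp5, Top2a and Sox4, as did 2 other probe sets for Esr1.

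**Figure D2:**
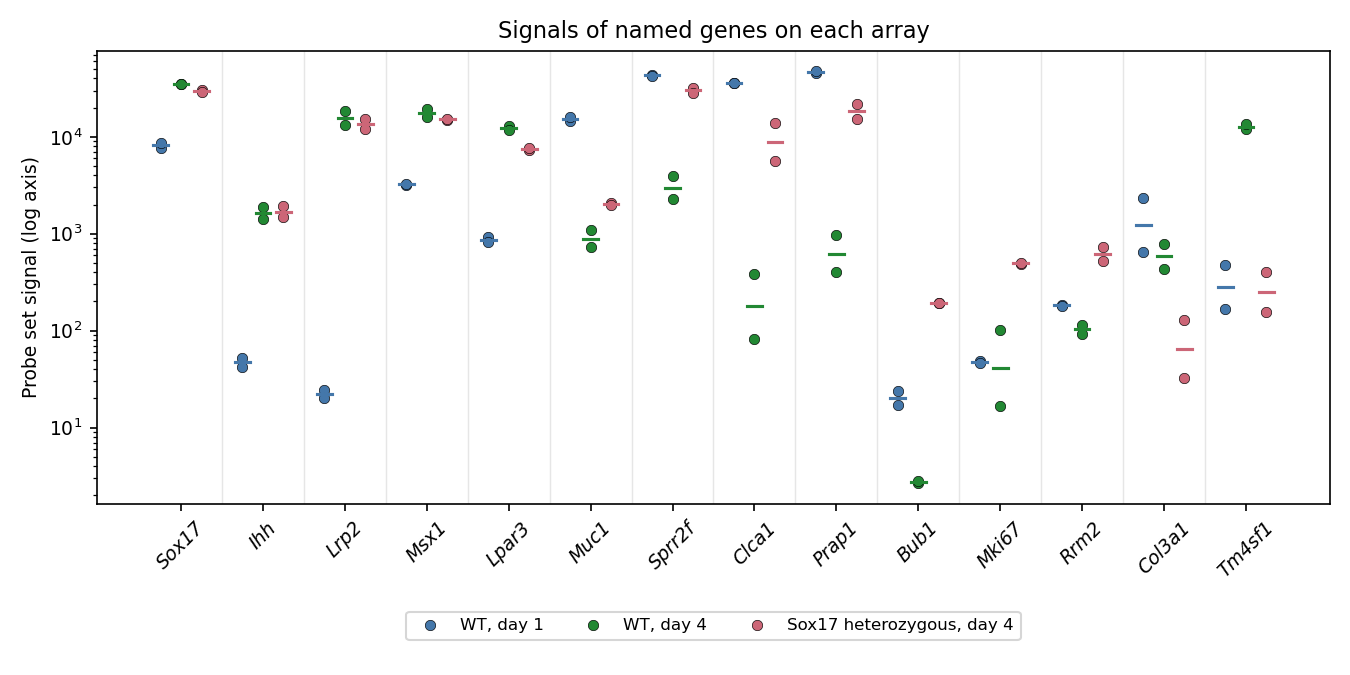
Probe set signal (log axis) of 14 named genes on each of the 6 arrays; dots are arrays and horizontal bars are geometric means of the 2 arrays of a group. Sprr2f reads 42997 on day 1, 2985 in WT on day 4 and 30243 in heterozygotes, and Tm4sf1 has WT day 4 signals of 11979 and 13528 against 155 and 403 in heterozygotes.

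The second comparison set Sox17 heterozygous epithelium against WT on day 4. Sox17 itself had signals of 30189 and 28810 in heterozygotes against 34794 and 35060 in WT (-0.24 ± 0.19, adjusted p = 0.586), a ratio of 0.845. At its other probe set it had 13304 and 13061 against 22781 and 18473, a ratio of 0.639 (-0.64 ± 0.23, adjusted p = 0.407 in the fit over every probe set). In that fit the first probe set had an adjusted p = 0.654. With an intensity trend the 2 adjusted p-values were 0.0761 for the other and 0.517 for the first. Whether these probe sets also read the GFP allele is unknown, so they do not check the genotype, and centring each array on its median gave 0.03 at the first. Mitotic, DNA replication and estrogen-induced epithelial genes were higher in heterozygotes as lists (medians 1.54, 0.40 and 1.24), and stroma, smooth muscle and macrophage markers lower (-1.22, -1.12 and -0.94). These calls had camera adjusted p-values from 2.47e-14 to 0.0430 and did not pass with an estimated correlation (adjusted p = 0.637) or with fry (0.0840 to 0.161). The membrane protein gene Tm4sf1 read 11979 and 13528 in WT and 155 and 403 in heterozygotes, and the secretory gene Prap1 970 and 399 in WT and 21826 and 15448 in heterozygotes.

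No single gene passed in limma's default fit: 0 of 18193 genes reached an adjusted p under 0.05, the smallest being 0.125, with 2406 at an unadjusted p under 0.05 where chance gives 910. With the spread modelled as a trend of intensity, an alternative chosen before the data were examined, 351 genes were higher and 289 lower at an adjusted p under 0.05. After centring on the median the trend fit had 149 higher and 59 lower. In simulated data of these groups the default fit found 6.55% of log2 changes of 3 among brighter genes and the trend fit 96.4%, with 6.54% false calls. The simulated spread was taken from the trend fit and was equal in all groups, which favours that fit. These rates therefore do not check the 351 and 289 calls. On the arrays the spread was not equal. Among the 6064 brightest genes the median absolute log2 difference was 0.25 in the WT day 4 pair and 0.12 in the heterozygous pair. The trend count was 110 without heterozygous array 253, 255 without 281, 1397 without WT array 284 and 208 after centring on the median, and 107 of the 640 genes remained called without array 253. At 2-fold and an unadjusted p under 0.05, 486 genes were higher and 1140 lower, a share of 29.9% higher. That share moved both ways, to 17.6% without array 284, 22.4% without 253 and 24.3% with the mean of a gene's probe sets, and to 41.8% after centring on the median, 43.7% without the dimmest genes, 49.1% after quantile normalization, 51.7% with a pseudocount of 100, 56.5% without array 277 and 58.9% above a mean signal of 200.

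None of the following 20 genes passed in the default fit. The errors after ± come from that fit, whereas the trend p-values come from the fit with an intensity trend, which has other errors. Higher in heterozygotes were the spindle checkpoint kinase Bub1 (5.70 ± 0.23, trend adjusted p = 0.00912), the epithelial secretory gene Clca1 (5.62 ± 0.88, trend adjusted p = 0.000819), Prap1 (4.88 ± 0.50, trend adjusted p = 0.000108), the cohesin acetyltransferase Esco2 (4.93 ± 0.25) and N-cadherin (Cdh2, 5.40 ± 0.81). Egfl6, Anxa9, the water channel Aqp5 and the lipase Lpl lay between 4.14 and 4.43, all past the trend threshold, and Birc5, which acts in cell division, at 4.20 ± 1.42 (trend adjusted p = 0.0764). Lower were Tm4sf1 (-5.66 ± 0.71, trend adjusted p = 0.000294), Fhod3 (-5.39 ± 0.51), the monoamine oxidase Maob (-5.34 ± 0.81), and the matrix genes Dpt (-4.69 ± 0.37), Bgn (-4.53 ± 0.62) and Col6a1 (-4.48 ± 0.90), also past it. Sox2 (-4.80 ± 0.72, trend adjusted p = 0.0421) and Sox2ot, an RNA transcribed across it (-4.40 ± 0.37, trend adjusted p = 0.0195), were both past it: Sox2ot read 575 and 512 in WT and 18 and 35 in heterozygotes. Vmn1r14 and Speer6-ps1 (-4.73 ± 0.96 and -4.49 ± 1.01) did not pass the trend threshold. Bub1 read 3 and 3 in WT and Esco2 2 and 2, and most of the lower genes read under 50 in heterozygotes, so the size and rank of these changes depend on the pseudocount of 1.

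Mitotic cell cycle genes were higher in heterozygotes in 26 of 27 cases, with a median of 1.54 (camera adjusted p = 2.47e-14, and adjusted p = 0.637 with an estimated correlation). This median was 0.79 without WT array 284, 2.08 without 277 and 0.98 with a pseudocount of 100. Of the 27 genes, 0 passed over all genes tested (8 adjusted over the list alone), and 5 did with an intensity trend (14 adjusted over the list alone). Anln was at 1.54 ± 0.27, Kif11 at 1.49 ± 0.25 and the proliferation marker Mki67 at 3.54 ± 0.87, with signals of 490 and 504 in heterozygotes against 102 and 17 in WT and 49 and 46 on day 1. DNA replication genes had a median of 0.40, 23 of 27 being above 0 (camera adjusted p = 2.23e-08, and adjusted p = 0.637 with an estimated correlation), with 0 past over all genes tested (5 adjusted over the list alone) and 5 with a trend. Their median was 0.67 after centring on the median, 0.16 with the mean of a gene's probe sets and 0.25 over every probe set. Rrm2, a subunit of ribonucleotide reductase, was at 2.56 ± 0.27 and Uhrf1 at 2.02 ± 0.34. Stroma, smooth muscle and macrophage markers were lower in the same arrays (medians -1.22, -1.12 and -0.94).

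Estrogen-induced epithelial genes had a median of 1.24 (camera adjusted p = 0.000321, and adjusted p = 0.637 with an estimated correlation). It was 0.63 without WT array 284, 1.94 without 277 and 0.77 over every probe set. Of the 14 genes, 0 passed over all genes tested (5 higher adjusted over the list alone), and 5 were higher with a trend. Sprr2f was at 3.34 ± 0.33 (trend adjusted p = 0.000117), Padi1 at 2.50 ± 0.58 and Muc1 at 1.19 ± 0.27 (trend adjusted p = 0.00781). Ltf had 27190 and 11735 in heterozygotes against 8351 and 1406 in WT (2.38 ± 0.97, trend adjusted p = 0.0780). Endoplasmic reticulum genes (median 0.28, camera adjusted p = 0.000528), immediate early genes (0.30, 0.000799) and epithelial junction genes (0.10, 0.0430) were also called up, each with an adjusted p = 0.637 with an estimated correlation. Of these, 0 genes passed over all genes tested, while 0, 1 and 1 were higher and 0, 0 and 1 lower adjusted over the list alone. With a trend, Xbp1 (0.94 ± 0.19), Pdia4 (0.78 ± 0.19), Myc (2.83 ± 0.41), Ier3 (1.07 ± 0.26), Hspa1a (1.27 ± 0.36) and the claudin Cldn4 (0.82 ± 0.24) passed upward, and Gja1 (-1.39 ± 0.23) and Hsph1 (-1.12 ± 0.37) downward. Without array 277 these 3 calls ended, at a median of 0.35 for endoplasmic reticulum (adjusted p = 0.0594), 0.17 for immediate early (0.169) and -0.00080 for junction genes (0.647), while after centring on the median the 3 calls stayed, at 0.55, 0.57 and 0.38. The junction call also ended after quantile normalization (median 0.06, 0.255), without the dimmest genes (0.09, 0.298), over every probe set (-0.05, 0.288), with the mean of a gene's probe sets (0.0051, 0.0716), above a mean signal of 200 (0.08, 0.725) and without array 281 (0.11, 0.0713).

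Stroma markers had a median of -1.22 (camera adjusted p = 0.00841), smooth muscle markers of -1.12 (0.0172) and macrophage and myeloid markers of -0.94 (0.0430), each with an adjusted p = 0.637 with an estimated correlation. Over all genes tested 0 of 20, 12 and 14 genes passed (3, 3 and 2 lower adjusted over the list alone), and 2, 1 and 0 were lower with a trend. The collagen Col3a1 read 433 and 788 in WT and 32 and 128 in heterozygotes (-3.16 ± 0.96), Synpo2 was at -3.26 ± 0.47 and the complement gene C1qa at -4.18 ± 0.59. Medians were -1.05 for endothelium, -1.07 for neutrophil, -0.96 for lymphocyte and -1.70 for erythrocyte markers (camera adjusted p = 0.172, 0.0729, 0.0925 and 0.373), and 0.16 for oviduct markers (0.713). In that order they were -0.85, -0.68, -0.49, -1.37 and 0.30 against array 284 alone, and -1.73, -1.61, -1.47, -1.85 and -1.50 against 277 alone. The dimmest 6065 genes had a median genotype change of -0.87, which was -0.14 against array 284 alone. Without array 277 the calls ended, at medians of -1.40 for stroma (adjusted p = 0.0682), -0.51 for smooth muscle and -0.36 for macrophages (0.275 for both). After quantile normalization the smooth muscle and macrophage calls ended, at medians of -0.48 and -0.79 (0.186 and 0.0712). The macrophage call also ended without the dimmest genes (median -0.25, 0.298) and without array 284 (-1.66, 0.0671). At an unchanged median it ended with an intensity trend (0.0678), with array weights (0.0535), and with only the 4 arrays compared or without array 302 or 303 (0.0611). The stroma call ended above a mean signal of 200 (median -1.16, 0.602). The smooth muscle median was -1.85 without array 284, -0.66 without 281 and -0.55 with a pseudocount of 32, and with a pseudocount of 100 the 3 medians were -0.50, -0.31 and -0.46. After centring on the median, endothelium (median -0.77, 0.0403), neutrophil (-0.80, 0.0136), lymphocyte (-0.69, 0.0109) and erythrocyte markers (-1.42, 0.0434) passed as lower too. Neutrophil markers also passed without array 284 (median -1.61, 0.0331), without 253 (0.0443), with only the 4 arrays compared or without 302 or 303 (0.0342), with the mean of a gene's probe sets (0.0475) and over every probe set (0.0271). Lymphocyte markers also passed without 284 (median -1.47, 0.0331), without 253 (0.0499) and over every probe set (0.0112).

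The other lists did not pass in the genotype comparison. Progesterone-induced genes had a median of -0.27 (camera adjusted p = 0.507; 0 adjusted over the list alone), with Ihh at 0.05 ± 0.27 and Cyp26a1, which breaks down retinoic acid, at 2.80 ± 1.29. Medians were 0.02 for steroid receptors and cofactors (0.405), 0.30 for glandular (0.308), -0.41 for luminal (0.836), -0.21 for implantation (0.502), 0.07 for cholesterol (0.119), -0.41 for WNT (0.836), -0.43 for Hedgehog (0.506) and -0.28 for Notch genes (0.506), with camera adjusted p-values in brackets. They were -0.21 for SOX genes (0.408), -0.13 for ion and water transport (0.770), -0.44 for prostaglandin (0.373), -0.52 for interferon (0.403), -0.06 for general epithelium (0.412) and 0.03 for the chromosome 1 neighbours (0.408). Glandular and cholesterol genes passed with the mean of a gene's probe sets (0.0373 and 0.0475) and over every probe set (0.0112 and 0.0271), and interferon genes above a mean signal of 200 (0.0440). Adjusted over the list alone, 1 luminal, 1 implantation, 2 transport and 1 interferon gene were higher, and 2 Notch, 1 SOX, 2 transport, 1 neutrophil, 1 lymphocyte and 1 oviduct gene lower, with 1 oviduct gene higher. With a trend, Hbegf (1.68 ± 0.22), Wnt4 (2.29 ± 0.51), Greb1 (2.44 ± 0.67) and the kinase Sgk1 (1.84 ± 0.24) were higher, and Lpar3 (-0.72 ± 0.20), Ptger2 (-1.04 ± 0.29) and the carbonic anhydrase Car2 (-1.50 ± 0.25) lower. Pgr (0.63 ± 0.51), Esr1 (-0.10 ± 0.29), Foxa2 (0.09 ± 1.02), Msx1 (-0.21 ± 0.20), Wnt7a (-0.41 ± 0.36) and Lif (0.50 ± 0.41) passed in neither fit. The median of all genes was -0.20, and it was -0.06 after quantile normalization and 0.07 after centring on the median, which turned the sign of the progesterone, implantation, SOX, transport and general epithelium medians. Camera's direction was up against a median below 0 for luminal, implantation, WNT, transport and general epithelium genes, and mean and median differed in sign for glandular (mean -0.06), luminal (0.26), general epithelium (0.03), oviduct (-0.51) and chromosome 1 genes (-0.12). Some other probe sets had the opposite sign for Gja1, Pdia4, Pgr, Wnt7a and Esr1.

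**Figure D3:**
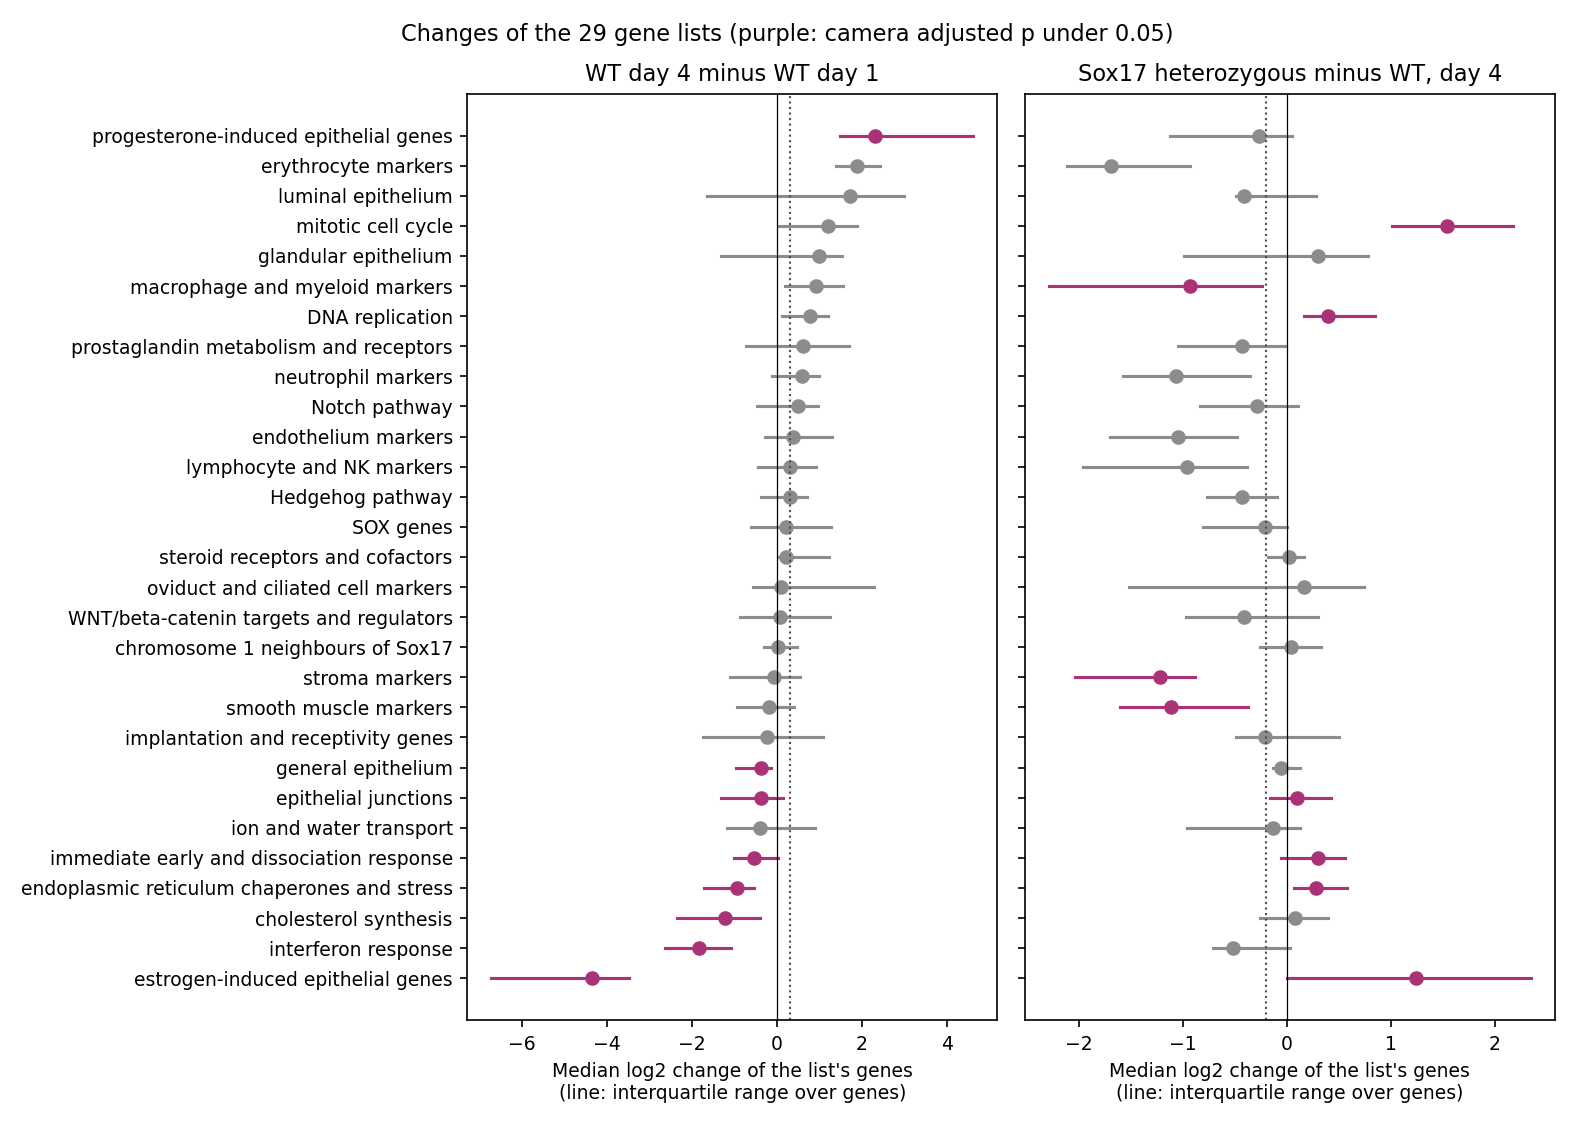
Median log2 change of each of 29 gene lists (dot) with the interquartile range over its genes (line), for WT day 4 minus day 1 (left) and heterozygous minus WT on day 4 (right); purple marks a camera adjusted p under 0.05 and the dotted line the median of all genes. Estrogen-induced genes have medians of -4.35 and 1.24, and mitotic genes of 1.20 and 1.54.

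The last comparison asked how the genotype changes relate to the day changes of the same genes. Genes that were lower on day 4 in WT tended to be higher in heterozygotes, such as Sprr2f (-3.85 ± 0.33 with day, 3.34 ± 0.33 with genotype), and Hbegf (-3.11 ± 0.22 and 1.68 ± 0.22). At 2-fold and an unadjusted p under 0.05, 281 genes were lower with day and higher in heterozygotes and 497 the reverse. In 100 simulations of unchanged groups, which also share the WT day 4 arrays, the means were 121 and 120.02 and the highest counts 150 and 151. In the same direction 39 were higher and 42 lower, against simulated means of 4.79 and 5.48. The simulations hold no day change, so counts above theirs, found in both directions, do not by themselves show opposition. Independent calls would give 44.3 and 147 opposed genes, and 62.6 higher and 104 lower in the same direction. That expectation leaves out the shared arrays.

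Across the 18193 genes, which are not independent replicates, the changes correlated at r = -0.43 (Spearman -0.48, covariance -0.63). Both comparisons use the same WT day 4 arrays with opposite sign, and the simulations gave a mean r of -0.50 and a covariance of -0.28. The observed covariance lay 0.34 further below 0 than the simulated one. The simulations gave all groups an equal spread, whereas the WT day 4 pair differed most, so the 0.34 may be too large. With array 277 for the day change and 284 for the genotype change, r was -0.17 and the covariance -0.28. With the reverse they were -0.049 and -0.10, and neither split shares an array.

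**Figure D4:**
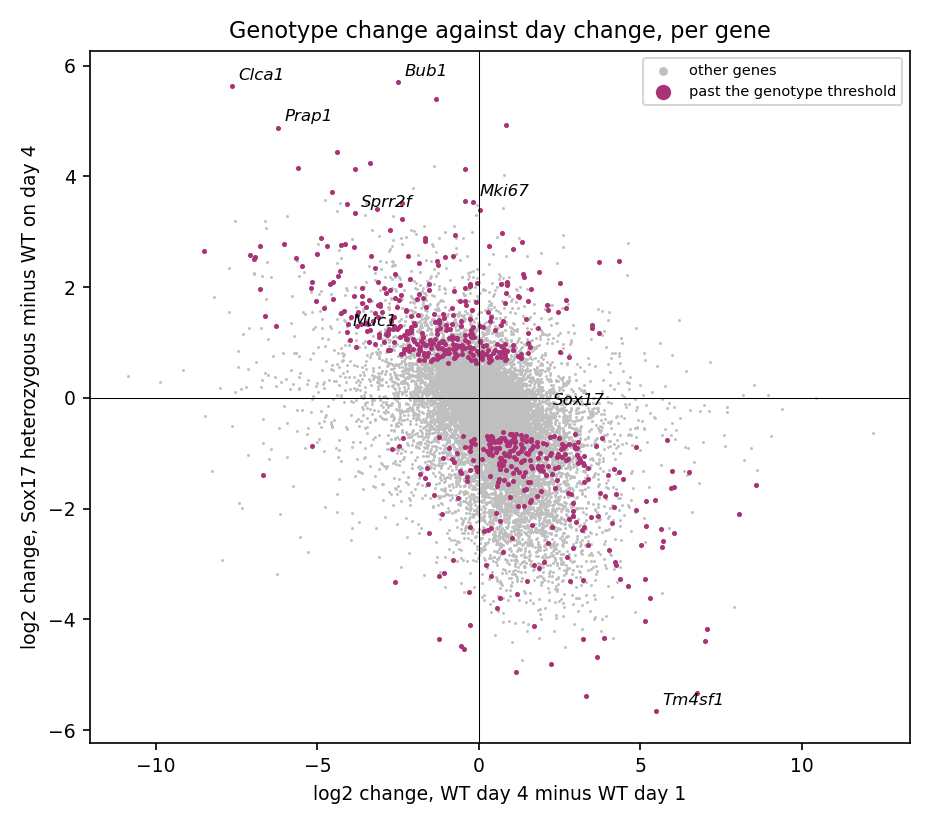
Genotype change (heterozygous minus WT on day 4, log2) against day change (WT day 4 minus day 1, log2), 1 dot per gene; purple dots are the 640 genes past the genotype threshold with an intensity trend. The changes of all genes correlate at r = -0.43, and both use the WT day 4 arrays, with opposite sign.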

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

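Pseudocounts of 32 and 100, a minimum mean signal of 200 and all variants of the trend fit were chosen after seeing the data; the other alternatives were fixed before. For the day comparison, the 2421 calls became 1469 after centring on the median, 3849 without the dimmest genes, 4506 with an intensity trend, 616 with only the 4 arrays compared, 1431 with array weights, 3908 at an adjusted p under 0.10, 4147 with a pseudocount of 100 and 4018 above a mean signal of 200. Leaving out 1 array gave 0 (without day 1 array 302 or 303) to 2459 calls; the lone array is then assumed to vary like the other groups, and fewer residual degrees of freedom remain. The 2-fold count of 3999 became 7382 over every probe set, 2559 with a pseudocount of 100, 2382 above a mean signal of 200, and 3440 to 5777 without 1 array.

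For genotype, the 0 calls became 11 without the dimmest genes, 640 with an intensity trend, 4 and 249 with pseudocounts of 32 and 100, and 554 above a mean signal of 200, and stayed at 0 without any 1 array. The 2-fold count of 1626 became 952 without the dimmest genes, 3131 over every probe set, 503 with a pseudocount of 100, 528 above a mean signal of 200, and 1333 to 3858 without 1 array. The trend counts of 4506 and 640 became 2481 and 208 after centring on the median, and 3177 to 5496 and 110 to 1397 without 1 array; all 640 genes kept their direction in each of these.

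Of the lists, 8 passed with day and 9 with genotype. With an estimated correlation 0 and 0 passed, with fry 16 and 0, and without 1 array 5 to 10 and 3 to 11, the lowest values without array 277. The 8 lists that passed with day by fry but not in the main test (steroid receptors, luminal, implantation, DNA replication, Hedgehog, SOX, prostaglandin and erythrocyte) had adjusted p-values from 0.0172 to 0.0475. The SOX list, with a median of 0.21 with day and down by camera, was up by fry (adjusted p = 0.0177), which does not set it against other genes. The correlation of the comparisons, -0.43, was -0.17 and -0.049 with the WT day 4 arrays split, -0.54 over genes past the day threshold, -0.39 without the dimmest genes, -0.46 after quantile normalization and over every probe set, and -0.60 to -0.38 without 1 array. Where no construction is named, the cause was not tested. Over named genes and alternatives, 445 day values lost and 68 gained a call, and 108 genotype values gained 1. In 4 day and 9 genotype cases a value called in neither fit changed sign by more than 1 standard error. Smaller changes of sign were not counted. Signal over background, which sets how well dim genes are measured, is unknown here.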

Other observations

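The medians of single gene lists, also those against 1 WT day 4 array, were planned; the shares regained, the pooled median of 46 markers, the most abundant markers, the comparisons with matched lists and with day 1, and the split of the day calls were chosen only after the results were seen. The genes that had fallen most with day did not come back alike in heterozygotes. The 288 genes covered fell at least 4-fold with day, passed with day in limma's default fit and had day 1 signals above 2000. Ltf, which did not pass with day, is not among them. The median share of the fall from day 1 to day 4 that was regained in heterozygotes (linear signals) was 3.70%, with an interquartile range of 0.262% to 14.1%. Of these genes, 100 regained under 1% and 5 over 50%. Those 5 were Sprr2f (68.1%) and, named after their values were seen, Mal (200.4%), Fuom (103%), Fndc1 (65.1%) and Trim2 (52.5%). Prap1 regained 38.6% and Clca1 24.5%. Lrg1 and Arg1, abundant on day 1, stayed at signals of 6 and 8 and of 46 and 31.

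Markers of other cell types were lower in heterozygotes, with a median change of -1.16 over the 46 stroma, smooth muscle and macrophage markers. Raised dim signals of WT array 277 are not the whole cause for stroma markers. Against array 284 alone these had a median of -1.40, below 100% of 10000 random lists matched on mean signal. The 46 markers together had -0.68, also below 100%. Smooth muscle and macrophage markers were below only 92.4% and 93.8%, which leaves this cause open for them. The random lists draw genes independently and 1 WT array was used. Of the 94 measured markers outside the oviduct list, 14 had a mean WT day 4 signal over 200. Whether the heterozygous preparations held fewer cells of other types stays open: against array 284 alone, 7 of 8 such lists had medians below those of their matched lists, by differences from -0.30 for macrophages to -1.35 for stroma, but oviduct markers lay above theirs by 0.43. The 5 most abundant of the 94 measured markers outside the oviduct list went different ways: Cd14, Nr2f2 and Lyz2 changed by -0.23 ± 0.19, 0.35 ± 0.20 and -0.21 ± 0.25, but Synpo2 and Col3a1 by -3.26 ± 0.47 and -3.16 ± 0.96, and without the dimmest genes the stroma and smooth muscle medians were -1.24 and -1.53 and the macrophage median -0.25. Enzymatic separation of the epithelium would remove most such cells, and an effect of the genotype on these genes was not tested and stays open.

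Mitotic genes were higher in heterozygotes than in either WT day 4 array, by medians of 0.79 against 277 and 2.08 against 284, each above 100% of 10000 matched lists. The rise thus did not rest on 1 WT array alone. Variation between animals is not excluded, since the list medians of 277 and 284 were themselves 7.36 and 6.13 (log2). The matched lists draw genes independently, while the mitotic list had an estimated correlation of 0.65, so they do not measure that variation. Dividing cells of other types stay open: oviduct markers had the highest median of 8 such lists, 0.16, above 98.6% of matched lists, though it was -1.50 against array 277 alone, and the other 7 lists had medians of -0.94 or below. Levels kept from day 1 do not account for it, since the mitotic genes lay above day 1 by a median of 2.82 (interquartile range 1.86 to 3.34), all 27 of them higher. The day 1 arrays had the lowest medians of this list, so they do not serve here as a reference for dividing epithelium. An effect of the genotype and a difference in stage between the animals were not tested and stay open.

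Genotype changes opposed day changes. Chance values of the shared WT day 4 arrays are argued against as the whole cause. A split used 1 array for the day calls, made with an intensity trend, and the other for the genotype change. Genes called down then lay above genes called up by 0.43 and 0.41 (log2, relative to matched lists). Day 1 tissue mixed into the heterozygous samples would bring all abundant day 1 transcripts back in 1 proportion, whereas the share regained had an interquartile range of 13.9 percentage points. An effect of the genotype and a difference in stage were not tested here either and stay open.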
